A study of Mus musculus with 117 samples.

How the data were processed

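RNA was measured in mouse CD4 T cells by RNA-seq, with TRIzol extraction and a stranded mRNA library kit per the labels' protocols. The 44 RNA samples used here formed 22 groups of 2 files, and each file gave 1 value for each of 10632 gene symbols. The deposited values are a normalised signal made by the authors: they are never negative, are not whole numbers, and carry no unit name in the files. Per the submitters' processing notes, the tools were Bowtie2 2.4.2.6, MACS2, HOMER, TopHat 1.3.2 and deepTools 3.1, with the builds mm9 and mm10, and which of them made the RNA values is not given in the sources used here. The ATAC-seq and ChIP-seq samples of the series were not used here. Read depth is unknown, so no counting interval or detection floor is given, and an exact 0 can be a failed estimate: transcripts that every cell uses, such as Rps27, were also near 0 in some profiles. Such a gene is described as listed at 0. Symbols are printed as in the files, which write a dot for a hyphen.

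Files were first compared in all 1892 ordered pairs. For each gene at 200 or more in the source file, the ratio of the files was taken as a whole percentage when the rounding of the printed values allowed one, with a tolerance of 0.011. The same step on simulated files called 100% of 71 genes in a scaled copy and 0% in a file with independent noise. In 27 pairs 100% of such genes had a whole-percentage ratio from 80 to 120, against a highest share of 11.0% and a median of 0 in all other pairs. These 27 files were therefore treated as derived from another file, and 17 separate profiles were left: 16 from regular stimulation and 1 from prolonged stimulation (Th2, 48 h). One cell of a derived file held an error text in place of the value of Ttc16.

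Each group thus has at most 1 separate profile. The tests planned before the data were examined, which took the files of a group as replicates, were not used as main results. Groups, gene lists, the rule for named genes and most alternative settings were fixed before the data were examined. The scaling and all tests below were chosen after the data were seen. Comparisons that needed derived profiles, such as prolonged against regular stimulation in Th1 or at later times, were not run, and the prolonged comparison at 48 h in Th2 took the place of those at 120 h. Values were scaled by median-of-ratios factors from the 6851 genes with a deposited value of at least 1 in all profiles. Differences are on log2(scaled value + 1), which understates the change of low genes. A pair of single profiles is described by the number of genes at least 2-fold apart with a scaled value of at least 5 in the higher profile, with no p-value.

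Comparisons in culture used limma 3.58.1 in R 4.3.3 on the differences between profiles of the same time, over the 3 cultured times of 48, 96 and 120 h. Steps in time used the differences within the 4 arms (Th1 and Th2, WT and Cxxc1 KO), and the 0 h comparison used 2 profiles against 2. A gene entered a test with at least 1 in 2 or more profiles, which left 9797 genes in culture, 10075 for steps in time and 8654 at 0 h. P-values were moderated, two-sided and adjusted by Benjamini-Hochberg over all genes tested, and a gene was called at an adjusted p under 0.05. Times may be of 1 culture series, and the labels do not say which profiles share cultures or animals. These p-values therefore measure only the spread between times, arms or 0 h profiles of these samples, which may be technical. A joint model over the 12 cultured profiles and a fit over 6 pairs were run first and replaced, because deviations of the KO effects correlated between lineages at 0.289 to 0.347, and those of the lineage effects between genotypes at 0.298 to 0.461.

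On simulated values with 200 changed genes, limma recovered 69% of 2-fold and 91% of 4-fold changes for KO against WT over 9797 genes, with 1.8% false calls. For the difference of KO effects between lineages, 45% and 77% were recovered. For Th2 against Th1 the shares were 69% and 90%, for 48 h against 0 h 80% and 100% over 10075 genes, and for 0 h 72% and 84% over 8654 genes. The simulated noise was drawn independently for each gene and each profile or difference. Correlation between genes was not simulated, so these shares may not hold for the fits on the data.

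A set of 32 gene lists was fixed before the data were examined, with 541 genes, of which 486 were found in the files: 8 names were matched through the dot spelling and 6 through older symbols, after the files were seen. Lists were tested against the other genes with camera from limma, with a preset correlation of 0.01 and Benjamini-Hochberg adjustment within each comparison. Of 282 list tests in 11 comparisons, 116 were called, and 0 were called with a correlation estimated from the few residuals, so list results are given with both p-values. Members of a list were also adjusted over the list alone. In the prolonged profile a list's median was ranked among 10000 random lists matched for size and expression in 20 level bins.

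The genes named are the 8 largest increases and decreases past the threshold for the main comparisons, and 2 each way for the others, with at least 5 in the higher group and without gene models that have no name of their own. Cxxc1, Trib3, the lineage panel and the members with the smallest adjusted p of each list described were added by the same rule. Alternatives were quantile normalisation, values as deposited, a pseudocount of 0.1, no filter, a mean of at least 5, the second files in place of the first, and each time, arm or 0 h profile left out. File comparisons and figures used Python 3.11.15 with numpy 2.4.6, pandas 2.3.3, scipy 1.17.1 and matplotlib 3.10.9.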

Results

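The RNA-seq part of the study followed splenic CD4 T cells of C57BL/6 mice from the naive state through Th1 and Th2 culture. Sorted naive CD4 cells were the 0 h samples under both the Th1 and the Th2 title. Cultured cells were activated through the T cell receptor and CD28 and taken at 48, 96 and 120 h. Th1 cultures held IL-2, IL-12 and an antibody to IL-4, whereas Th2 cultures held IL-2, IL-4 and an antibody to IFN-γ. Cells came from wild-type (WT) mice or from mice with floxed Cxxc1 and a CD4-Cre transgene, here called Cxxc1 KO. Cxxc1 encodes a protein that binds unmethylated CpG and belongs to the SET1 complexes, which methylate histone H3 at lysine 4. WT cultures were also given prolonged stimulation. The comparisons ask what the deletion, the lineage, the time and the stimulation change.

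The 22 groups had 2 files each, but only 17 of the 44 files were separate profiles. In the other 27 files each gene's value equalled its value in another file times a whole percentage between 80 and 120. This held for 100% of the 48 to 150 genes at 200 or more in each pair, within a tolerance of 0.011. The 2823 factors pooled over the 27 pairs had a median of 100%. Derived and source files differed in at most 1 gene as to whether the value was 0, against 105 to 526 genes between separate profiles. That 1 gene was Ttc16, through the error text read as 0. All second files were derived in this way. The Th1 prolonged profiles at 48, 96 and 120 h derived from the Th1 WT regular profile at 48 h, and the later Th2 prolonged profiles from the Th2 prolonged profile at 48 h. A derived file was not counted as a sample, so each group had at most 1 profile. The Th1 prolonged groups and the later Th2 prolonged groups had none of their own. No value below has a replicate of its own group. Differences within a time have no replicate check, and the tests over times or arms measure the spread between times or arms. Values summed to between 101977 and 220708 per separate profile and the depth behind them is unknown. As deposited, genes at 120 h had a median log2 difference of −0.67 between Cxxc1 KO and WT in Th1 and −0.57 in Th2 cultures, so changes are given relative to that shift, after scaling.

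**Figure D1:**
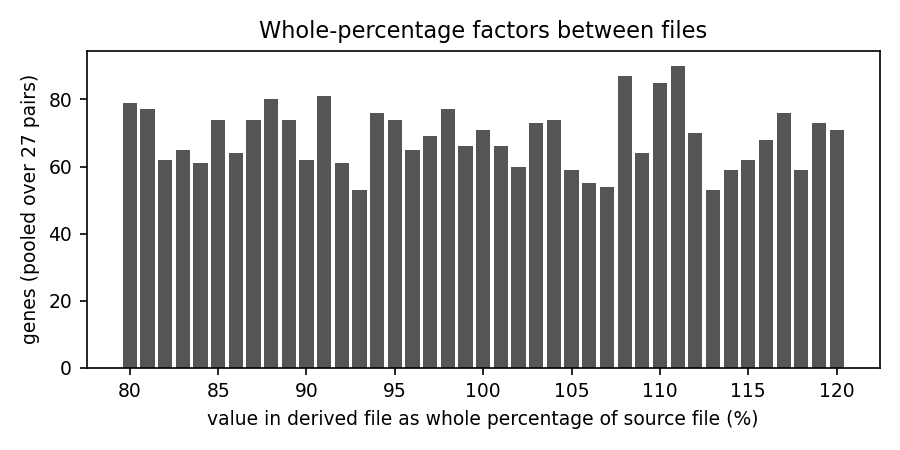
Number of genes (vertical axis, 2823 gene values pooled over 27 pairs of files) at each whole percentage (horizontal axis, from 80 to 120%) that the value in a derived file made of the value in its source file. Genes at 200 or more in the source file are shown, and the median factor was 100%.

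The targeted transcript was clearly lower in every cultured Cxxc1 KO profile, with no clear fall at 0 h. In WT profiles scaled Cxxc1 values at 0, 48, 96 and 120 h were 16.24, 8.77, 11.84 and 10.95 under the Th1 title and 16.12, 10.23, 12.13 and 9.11 under the Th2 title. The Cxxc1 KO profiles had 14.67, 3.01, 2.4 and 3.13 in Th1 and 16.01, 1.73, 2.44 and 3.02 in Th2. In culture Cxxc1 fell by 1.67 on the log2 scale (SE 0.12, n = 3 times, limma adjusted p = 0.0132), and it was lower in 6 of 6 pairs. At 0 h the difference was −0.07 (SE 0.10), so the labels of the 0 h profiles are not checked by the targeted gene, and these are called the profiles labelled Cxxc1 KO. Mid1, which encodes a microtubule-associated ubiquitin ligase, separated the genotypes at all times. It lay between 4.70 and 8.0 in the 8 profiles labelled Cxxc1 KO and between 0.37 and 1.14 in the 8 WT profiles of regular stimulation. Without 96 h or without 120 h the Cxxc1 difference was −1.55 or −1.79 and no longer passed over all genes. The prolonged WT profile had a Cxxc1 value of 7.47.

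**Figure D2:**
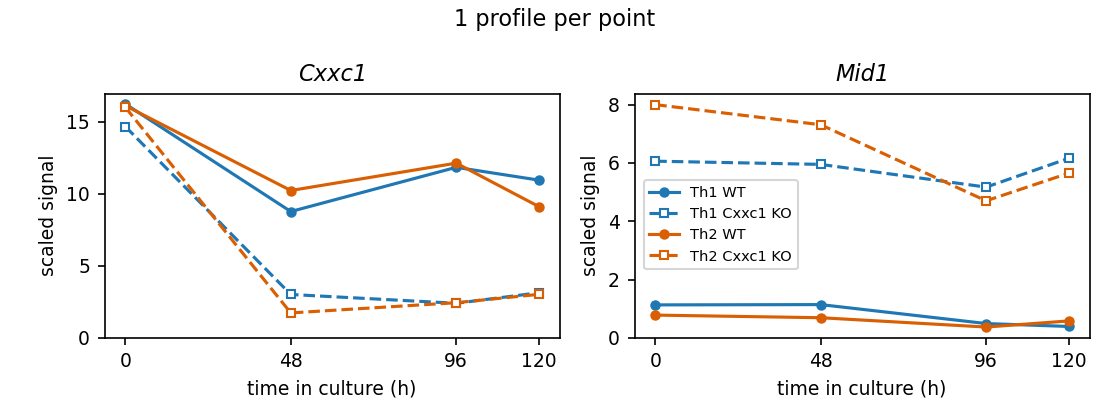
Scaled signal (vertical axis) of Cxxc1 and Mid1 by hours in culture (horizontal axis) in WT and Cxxc1 KO cells under the Th1 and Th2 titles, with 1 profile per point and no error bar. Cxxc1 lay at 14.67 to 16.24 in the 4 profiles at 0 h, and Mid1 lay above 4 in each profile labelled Cxxc1 KO.

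With both lineages pooled, Cxxc1 KO cells in culture had higher Mid1 and lower Cxxc1, Myo6, Ankrd37 and Slc16a3 than WT cells. Some interferon-response genes rose as well, with unequal values in the lineages: Usp18 differed by 1.68 in Th1 and 0.27 in Th2, Gbp10 by 1.41 and 0.20, and Mx1 by 1.60 and 0.85. Mid1 rose by 2.09 (log2, SE 0.10, n = 3 times, adjusted p = 0.00166), from a mean scaled value of 0.61 to 5.82. Mx1, an antiviral GTPase, rose by 1.23 (SE 0.13, adjusted p = 0.0418), and Usp18, which removes ISG15 from proteins, rose by 0.97 (SE 0.10, adjusted p = 0.0418). The other largest increases were Psrc1 at 1.31 and Il15ra, the receptor chain that presents IL-15, at 1.17. Trex1, a cytosolic DNA exonuclease, rose by 1.05, Slfn8 by 0.86, the interferon-induced GTPase Irgm2 by 0.84 and Gbp10 by 0.81, each at an adjusted p of 0.0467. Myo6, a myosin motor, fell by 1.06 (SE 0.10, adjusted p = 0.0418). Ankrd37 fell by 0.94 and Slc16a3, a lactate exporter, by 0.87, both at an adjusted p of 0.0467. Limma called 22 of 9797 genes, 18 higher and 4 lower in Cxxc1 KO, with 2059 at an unadjusted p under 0.05, and 9 of the 22 were at least 2-fold apart. This count moved with the times and the handling of low values: 253 genes were called with a mean of at least 5 (98 higher, 155 lower), 970 without 48 h, 0 without 96 h (945 unadjusted), 0 without 120 h (1050 unadjusted) and 0 with a pseudocount of 0.1 (1816 unadjusted). As deposited, where the median of expressed genes was −0.34, 120 genes were called higher and 951 lower.

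In the lineage panel over both lineages 0 of 11 genes passed over all genes (limma, 2059 of 9797 unadjusted), and 3 of 11 genes rose and 3 fell when adjusted over the list alone. The 3 that rose were Ifng, the Th1 cytokine (0.79, SE 0.12, adjusted p over all genes 0.0589), Il12rb2, the IL-12 receptor chain (0.71, SE 0.19), and Tbx21, the Th1 master regulator T-bet (0.32, SE 0.10). Il10 (−0.67, SE 0.10), Il4 (−0.44, SE 0.10) and the chemokine receptor gene Ccr8 (−0.34, SE 0.10) were the 3 that fell. The pooled values of these 3 came mostly from Th2, at −1.18, −0.69 and −0.61. In Th1 they were −0.16, −0.19 (SE 0.26) and −0.07. Il10 lay near 0 in Th1, at a mean scaled value of 0.13 in Cxxc1 KO and 0.32 in WT. Ifng was higher in the profile labelled Cxxc1 KO in 8 of 8 pairs, those at 0 h included. Gata3, which encodes the Th2 master regulator, differed by 0.02 (SE 0.11), Il5 by 0.05, Il13 by 0.07, Cxcr3 by 0.08 and Il18r1 by −0.12, none past the test. Trib3, a pseudokinase induced by amino acid stress, differed by −0.46 (SE 0.23, adjusted p = 0.304). Neither the Th1 program (median 0.11) nor the Th2 program (median 0.00) moved as a list. Of 14 subunits of the H3K4 methyltransferase complexes, 1 fell, Cxxc1 itself, and the median was −0.01.

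Genes of the p53 response were higher in cultured Cxxc1 KO cells. Of 18 members, 16 rose when adjusted over the list alone and 0 over all genes (limma), with a median of 0.88 (adjusted p = 3.49e-12, and adjusted p = 0.625 with an estimated correlation). Phlda3, an Akt inhibitor, rose by 1.73 (SE 0.26), Plk2 by 1.59 (SE 0.26), the BH3-only gene Bbc3 by 1.28 (SE 0.20) and the death receptor gene Fas by 1.13 (SE 0.18), each at 0.00235 over the list. Cdkn1a, the p21 cell cycle inhibitor, was higher in Cxxc1 KO in 6 of 6 cultured pairs, for example at 14.68 against 1.64 in Th1 cultures at 96 h. The list's median was 0.37, 1.28 and 1.10 at 48, 96 and 120 h. CD8 T cell markers were higher too, but already at 0 h, where the p53 list had a median of −0.02. Summed Cd8a and Cd8b1 were higher in the profile labelled Cxxc1 KO in 8 of 8 pairs (7 of 8 as deposited), at most 9.24 against at most 4.56 in WT. Both genes rose when adjusted over the list alone, Cd8b1 by 0.64 (SE 0.11) and Cd8a by 0.56 (SE 0.11).

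Interferon-stimulated genes were higher in Th1 cultures of Cxxc1 KO cells (median 0.96) and not in Th2 cultures (median −0.07). With both lineages pooled, 14 of 22 rose when adjusted over the list alone and 2 over all genes, with a median of 0.47 (adjusted p = 2.15e-10, and adjusted p = 0.625 with an estimated correlation). Besides Mx1 and Usp18, Irf7, a transcription factor of the interferon response, rose by 0.98 (SE 0.19) and Mx2 by 0.82 (SE 0.12) over the list alone. As deposited, the list's median at 120 h was −0.15, whereas scaled it was 0.27. Genes of the IFN-γ response and antigen presentation had a median of 0.31, which was 0.00 as deposited, and 15 of 21 rose when adjusted over the list alone and 0 over all genes. The list's adjusted p was 9.1e-10, and adjusted p = 0.501 with an estimated correlation. Iigp1 rose by 0.89 (SE 0.13), Gbp5 by 0.88 (SE 0.14) and Igtp by 0.81 (SE 0.12), all interferon-induced GTPases.

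Proliferation, sterol and glycolysis genes were lower in cultured Cxxc1 KO cells. All 26 replication-dependent histone genes fell when adjusted over the list alone and 0 over all genes, with a median of −0.66 (adjusted p = 1.12e-17, and adjusted p = 0.625 with an estimated correlation). Hist1h1b fell by 0.83 (SE 0.17) and Hist1h2ae by 0.73 (SE 0.15), and as most histone mRNAs lack a poly(A) tail their level in an mRNA library also depends on how they are captured. Of 32 mitotic and replication genes, 23 fell over the list alone and 0 over all genes, with a median of −0.38 (adjusted p = 1.71e-15, and adjusted p = 0.625 with an estimated correlation). Plk1, a mitotic kinase, fell by 0.80 (SE 0.15), the proliferation marker Mki67 by 0.69 (SE 0.13) and the topoisomerase gene Top2a by 0.56 (SE 0.12). Of 19 cholesterol biosynthesis genes, 18 fell over the list alone and 0 over all genes, with a median of −0.54 (adjusted p = 1.17e-14, and adjusted p = 0.625 with an estimated correlation). Hmgcs1, which makes HMG-CoA, fell by 0.93 (SE 0.15), and Idi1 by 0.59 (SE 0.10). Among 17 glycolysis genes, 11 fell over the list alone and 1, Slc16a3, over all genes, with a median of −0.42 (adjusted p = 1.77e-09, and adjusted p = 0.625 with an estimated correlation). Ldha, lactate dehydrogenase, fell by 0.61 (SE 0.12) and Tpi1 by 0.57 (SE 0.11). In Th1 cultures at 96 h the sign of the glycolysis median turned after quantile normalisation. The T cell identity list had a median of −0.15 and the heat shock list of −0.14, with no member past the test (both lists adjusted p = 0.0371, and adjusted p = 0.625 and 0.668 with an estimated correlation). Quantile normalisation put the T cell identity median at 0.00. The markers of CD8 T cells were higher in these same profiles, in 6 of 6 cultured pairs, B cell markers in 2 of 6 and NK cell markers in 1 of 6.

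**Figure D3:**
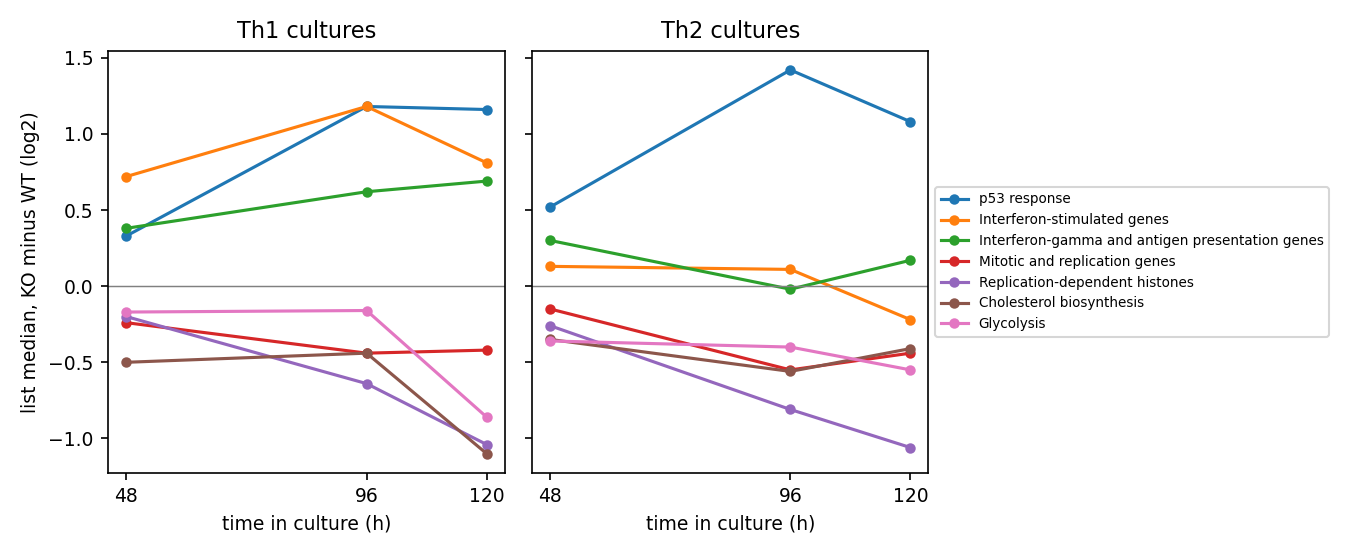
Median log2 difference between Cxxc1 KO and WT (vertical axis, scaled values) of 7 gene lists by hours in culture (horizontal axis) in Th1 and Th2 cultures, 1 difference per gene and time. The p53 median reached 1.42 in Th2 at 96 h and the histone median −1.06 in Th2 at 120 h, and interferon-stimulated genes lay at 0.72 to 1.18 in Th1. With other scalings the sign turned for interferon-stimulated genes in Th2 at 96 h (−0.06 as deposited), IFN-γ genes in Th2 at 120 h (−0.38 as deposited) and 96 h (0.10 after quantile normalisation), and glycolysis in Th1 at 96 h (0.06 after quantile normalisation).

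In Th1 cultures taken alone, Cxxc1 KO cells had higher interferon-stimulated transcripts. Mid1 rose by 2.04 (SE 0.16, n = 3 times), Usp18 by 1.68 (SE 0.16), Mx1 by 1.60 (SE 0.13), Gbp10 by 1.41 (SE 0.12) and Trex1 by 1.3 (SE 0.12), and Cxxc1 fell by 1.58 (SE 0.15), each at an adjusted p between 0.0477 and 0.0495. All 22 interferon-stimulated genes rose when adjusted over the list alone and 2 over all genes, with a median of 0.96 (adjusted p = 2.21e-19, and adjusted p = 0.546 with an estimated correlation). Irf7 rose by 2.02 (SE 0.30) and Bst2, a viral tethering factor, by 1.01 (SE 0.13). Of the IFN-γ response list 16 of 21 rose over the list alone and 0 over all genes, with a median of 0.46 (adjusted p = 4.66e-14, and adjusted p = 0.546 with an estimated correlation). The CD8 marker genes rose beside them over their list alone, Cd8b1 by 0.85 (SE 0.15). Of the p53 list 14 of 18 rose over the list alone, of the cholesterol list 19 of 19 fell, of the histones 22 of 26 and of the mitotic genes 18 of 32, with medians of 0.83, −0.61, −0.61 and −0.38. For each of these 4 lists the result was adjusted p = 0.546 with an estimated correlation. Ifng differed by 0.78 (SE 0.18, adjusted p = 0.152), Tbx21 by 0.45, Il12rb2 by 0.82, Gata3 by −0.12, Il4 by −0.19 and Trib3 by −0.44. Limma called 7 of 9797 genes, 6 higher and 1 lower (1576 unadjusted), or 111 higher and 450 lower as deposited. It called 0 without 48 h (1977 unadjusted), 0 without 96 h (796) and 0 without 120 h (979).

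In Th2 cultures taken alone, Mid1 was the single gene called, with a rise of 2.14 (SE 0.12, n = 3 times, adjusted p = 0.00804), and Cxxc1 differed by −1.77 (SE 0.17, adjusted p = 0.0655). Among 19 genes of the Th2 program 5 fell and 2 rose when adjusted over the list alone, and 0 over all genes. Il10 fell by 1.18 (SE 0.13, adjusted p over all genes 0.0801), from a scaled value of 16.43 to 7.08 at 120 h, and the cytokine gene Il24 fell by 0.92 (SE 0.13). Ccr8 fell by 0.61 (SE 0.14), Ecm1 by 0.57 (SE 0.13) and Il4 by 0.69 (SE 0.20). The Th2 list did not move as a whole (adjusted p = 0.0912). Gata3 differed by 0.17, Ifng by 0.80 (SE 0.17, adjusted p = 0.151) and Trib3 by −0.49. Of 18 p53 response genes 16 rose over the list alone and 0 over all genes (median 0.94, adjusted p = 8.37e-14, and adjusted p = 0.753 with an estimated correlation). Phlda3 rose by 1.72 (SE 0.22) and Ccng1 by 1.41 (SE 0.22). Over their lists alone 25 of 26 histones fell (median −0.69) and 17 of 32 mitotic genes (median −0.41), both with adjusted p = 0.753 with an estimated correlation. Likewise 14 of 17 glycolysis genes fell (median −0.46) and 12 of 19 cholesterol genes (median −0.48), both with adjusted p = 0.509 with an estimated correlation. Interferon-stimulated genes had a median of −0.07 with no member past the test (adjusted p = 0.655). Summed CD8 markers were again higher in Cxxc1 KO, at 6.11 against 4.25 at 120 h. Limma called 1 gene of 9797 (1682 unadjusted), or 119 higher and 712 lower as deposited. The call was lost with a pseudocount of 0.1 (1467 unadjusted), without 96 h (818 unadjusted) and without 120 h (893 unadjusted), and 7 genes were called without 48 h.

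Whether the deletion acted differently in the 2 lineages was tested as the difference of the KO effects, Th2 minus Th1. Limma called 0 of 9797 genes (698 unadjusted), and the smallest adjusted p was 0.212. Interferon-stimulated genes differed most: all 22 were lower when adjusted over the list alone and 0 over all genes, with a median of −0.97 (adjusted p = 2.38e-31, and adjusted p = 0.219 with an estimated correlation). Irf7 differed by −2.08 (SE 0.27), Isg15 by −1.90 (SE 0.24), Xaf1 by −1.17 (SE 0.13) and Bst2 by −1.05 (SE 0.13). In the IFN-γ list 2 of 21 genes, Gbp6 (−1.01, SE 0.15) and Irgm1 (−0.81, SE 0.18), were lower over the list alone. Across 10075 genes, which are not independent replicates, the KO effects of the lineages correlated at Pearson's r = 0.157 at 0 h, 0.201 at 48 h, 0.582 at 96 h and 0.564 at 120 h (Spearman's rho 0.143, 0.21, 0.576 and 0.53). No p is given for these 4 correlations.

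At single times the number of genes at least 2-fold apart between Cxxc1 KO and WT grew with time in culture, with no replicate check. In Th1 cultures 51 genes differed at 48 h (36 higher, 15 lower), 113 at 96 h (87 and 26) and 196 at 120 h (87 and 109). In Th2 cultures 30 genes differed at 48 h (15 and 15), 99 at 96 h (71 and 28) and 197 at 120 h (79 and 118). The direction depended on the scaling. Quantile normalisation gave 90 and 76 in Th1 and 94 and 90 in Th2 at 120 h, and without the value floor the splits were 309 and 121, and 295 and 143. As deposited, all genes shifted by a median of −0.28 in Th1 and −0.26 in Th2 at 96 h. The splits were then 26 and 22, 59 and 104, and 14 and 959 in Th1, and 53 and 147 at 96 h and 17 and 627 at 120 h in Th2. The profiles differed in genes listed at 0 as well. In Th1 these numbered 199 in Cxxc1 KO and 213 in WT at 48 h, and 91 and 361 at 120 h. In Th2 they numbered 176 and 261 at 48 h, and 82 and 178 at 120 h. How much of the growth with time comes from such differences between libraries was not tested. At 0 h, before any culture, 11 genes were 2-fold apart between the WT profiles and 13 between the profiles labelled Cxxc1 KO. These pairs hold no spread between cultures, so they are no yardstick for the counts in culture.

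At 120 h in Th1 cultures the p53 target gene Phlda3 had the largest increase in Cxxc1 KO, 2.68 on the log2 scale. Scaled values in Cxxc1 KO and WT were 10.31 and 0.76 for Phlda3, 9.12 and 0.64 for the protease inhibitor gene Serpine2, 7.56 and 0.70 for the DNA repair gene Mgmt, and 5.16 and 0.42 for Cox6b2. Tmem176a had 12.43 and 1.87, Tmem176b had 17.09 and 3.46, and Mid1 had 6.16 and 0.39. Lower in Cxxc1 KO were the integrin gene Itga7 (2.12 and 17.45), the oxidoreductase gene Ero1l (13.50 and 50.67) and Trat1, a T cell receptor adaptor (6.92 and 22.59). Hmgcs1 (17.47 and 56.84), Sc4mol (10.26 and 32.54) and Mvd (4.58 and 15.39) of cholesterol synthesis, and the desaturase gene Scd1 (−1.58), were lower as well. Rprl1 was listed at 0 in WT (5.24 in Cxxc1 KO) and Slpi was listed at 0 in Cxxc1 KO (6.87 in WT).

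At 120 h in Th2 cultures Serpine2 (7.05 and 0.44), Mgmt (9.51 and 0.94), Hmgn3 (7.20 and 0.35), Dcxr (8.62 and 1.14) and Cox6b2 (a log2 difference of 2.13) were higher in Cxxc1 KO than in WT. The defensin gene Defa4, which has near-identical copies and is uncertain, had 11.08 and 1.31, and Bc1 (16.60) and Defb28 (8.53) were listed at 0 in WT. Trat1 lay at 12.80 in Cxxc1 KO and 80.03 in WT, the interferon-induced genes Ifi27l2a at 26.02 and 146.94 and Ifitm1 at 1.5 and 10.08, and Itga7 at 4.48 and 21.53. Gzmb, granzyme B, lay at 185.80 and 721.22, Gp49a at 6.87 and 32.10, Crmp1 differed by −1.90 and AA467197 by −1.86. Over the cultured pairs of both lineages Serpine2 was higher in Cxxc1 KO in 6 of 6, Mgmt in 5, Trat1 in 2 and Itga7 in 1.

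At 48 h in Th1 cultures Bc1 (23.80) and Atp6v0c (14.13) were listed at 0 in WT and Insl3 at 0 in Cxxc1 KO (8.79 in WT), while Angptl2 had 4.25 in Cxxc1 KO and 16.27 in WT. At 96 h in Th1 the extremes were Rprl3 (2.76), Atp6v0c.ps2 (20.09, listed at 0 in WT), Oaz1.ps (−4.06) and Atp6v0c (listed at 0 in Cxxc1 KO, 18.99 in WT). Atp6v0c thus changed sides between times, and such pseudogene and parent pairs share reads and are uncertain. In Th2 at 48 h Mid1 differed by 2.30, Defb46 was listed at 0 in WT, and Defa4 and Snhg9 were listed at 0 in Cxxc1 KO. In Th2 at 96 h Dcxr differed by 2.83, Plk2 by 2.54, Cxxc1 by −1.93 and Plac8 by −1.92.

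Before culture, Hbb.b1 and AA465934 were lower in the profiles labelled Cxxc1 KO than in WT, and no other gene passed over all genes. Mid1 differed by 2.03 (SE 0.16, adjusted p = 0.0681, n = 2 profiles of each label, limma). Both profiles of a label were naive cells that may share animals, so the spread behind the p-values at 0 h may be technical. Hbb.b1, a β-globin gene, fell by 3.71 (adjusted p = 0.000479): it was listed at 0 in both profiles labelled Cxxc1 KO against 11.70 and 12.43 in WT. Its near-identical copies make this call uncertain. AA465934 fell by 1.75. Of 19 Th1 program genes 4 rose when adjusted over the list alone and 0 over all genes, with a median of 0.19 (adjusted p = 4.01e-05, and adjusted p = 0.401 with an estimated correlation). They included the chemokine genes Ccl3 (1.10, SE 0.13) and Ccl4 (0.73, SE 0.12) and Ifng (0.76, SE 0.11). Both CD8 marker genes rose over their list alone, Cd8b1 by 0.95 (SE 0.24) and Cd8a by 0.85 (SE 0.23), beside these effector genes. Of 9 erythroid and platelet markers 5 fell over the list alone and 1 over all genes, with a median of −0.45 (adjusted p = 1.85e-06, and adjusted p = 0.401 with an estimated correlation), and their sum was 992.64 and 1050.98 in WT against 651.05 and 834.08. Tbx21 differed by 0.21, Gata3 by 0.07 and Trib3 by −0.08. Limma called 2 of 8654 genes, both lower (776 unadjusted), or 2 higher and 2 lower as deposited. It called 1 or 2 when any of the 4 profiles was left out.

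Counted per pair, 19 genes were 2-fold apart at 0 h under the Th1 title (9 higher, 10 lower; 10 and 6 as deposited) and 15 under the Th2 title (6 higher, 9 lower). Mid1 differed by 1.73 and 2.34 in these pairs. Defb48.ps (5.62) was listed at 0 in the first WT profile and Rprl3 at 0 in its counterpart labelled Cxxc1 KO (9.28 in WT). Rps27 differed by 1.39 in the second pair, and Defa.ps1 (8.11 in WT) was listed at 0 in the profile labelled Cxxc1 KO. Pairs of the same label also had genes 2-fold apart. Between the WT profiles (6 and 5 genes; 4 and 5 as deposited) these included Snhg9, Usmg5 (1.38), Rpl30 (−1.57) and Snhg3 (−1.18). Between the profiles labelled Cxxc1 KO (6 and 7; 6 and 11 as deposited) these included Defa4, Rprl3, Defb48.ps and Ndufb6 (−1.49).

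Th2 and Th1 cultures differed by the Th2 program over both genotypes. Gata3 rose by 2.46 in Th2 against Th1 cultures (SE 0.18, n = 3 times, adjusted p = 0.00845), from a mean scaled value of 7.78 to 44.51, and Il4 by 2.38 (SE 0.19, adjusted p = 0.011). Ecm1, an extracellular matrix protein gene, rose by 2.87 (SE 0.37, adjusted p = 0.0304), from 10.40 to 120.45, Tanc2 by 2.82 (SE 0.12), Epas1, which encodes HIF-2α, by 2.77 (SE 0.44) and the transcription factor gene Nfil3 by 2.66 (SE 0.27). Pros1, protein S, rose by 2.46 (SE 0.10) and the caspase gene Casp6 by 2.30 (SE 0.11). Ms4a4b fell by 2.90 (SE 0.26, adjusted p = 0.0151), from 56.85 to 8.81, and the interferon-inducible genes Ifi203 by 1.94 (SE 0.10) and Mndal fell by 1.90 (SE 0.19). Ms4a4c (−1.75), Nsg2 (−1.63), Nrn1 (−1.48), Ms4a6b (−1.46) and Ifitm3 (−1.44, SE 0.21, adjusted p = 0.043) fell as well. The Th1 signature genes Ifng (0.10, SE 0.11), Tbx21 (0.02, SE 0.10), Il12rb2 (−0.23) and Cxcr3 (−0.20) were not called. Il18r1 differed by −1.66 (SE 0.33, adjusted p = 0.0834), Il13 by 1.22 (SE 0.26, adjusted p = 0.0962), Il10 by 2.27 (SE 0.51, adjusted p = 0.115), Il5 by 0.56, Cxxc1 by −0.10 and Trib3 by 0.33. Limma called 156 of 9797 genes, 92 higher and 64 lower in Th2 (1738 unadjusted), and 90 of them were at least 2-fold apart. It called 711 without 48 h, 26 without 96 h, 18 without 120 h and 17 with a pseudocount of 0.1.

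**Figure D4:**
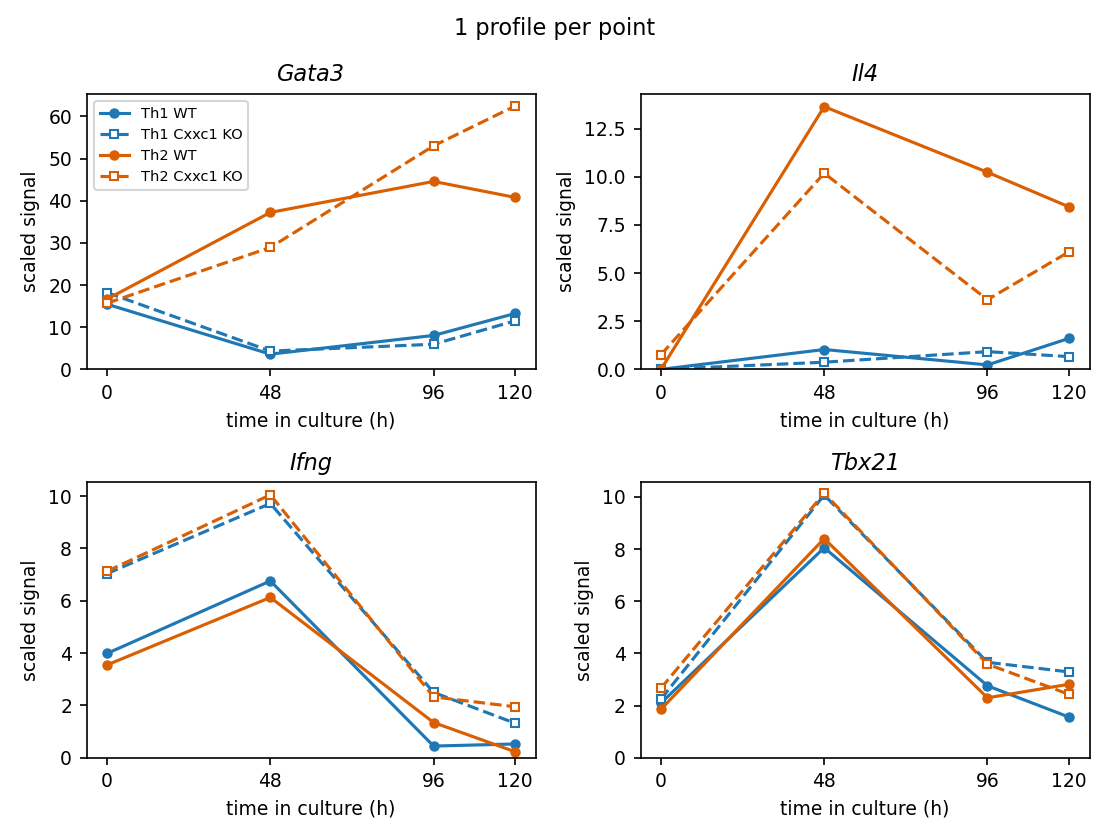
Scaled signal (vertical axis) of Gata3, Il4, Ifng and Tbx21 by hours in culture (horizontal axis) in WT and Cxxc1 KO cells under the Th1 and Th2 titles, with 1 profile per point and no error bar. Gata3 lay at 28.92 to 62.50 in Th2 cultures, and Ifng was highest in each arm at 48 h, at 6.13 to 10.05.

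By list, all 19 genes of the Th2 program were higher in Th2 cultures: 16 rose when adjusted over the list alone and 9 over all genes, with a median of 1.87 (adjusted p = 8.89e-18, and adjusted p = 0.44 with an estimated correlation). Besides Gata3 and Il4, the chemokine receptor genes Ccr4 rose by 1.89 (SE 0.11) and Ccr8 by 1.65 (SE 0.10). Of 20 Th1 program genes 8 fell and 1 rose over the list alone, and 0 over all genes, with a median of −0.48 (adjusted p = 0.000425, and adjusted p = 0.44 with an estimated correlation). Nkg7, a granule protein gene, fell by 0.92 (SE 0.17) and Tnf by 0.94 (SE 0.18). Interferon-stimulated genes fell, 15 of 22 over the list alone and 4 over all genes, with a median of −0.51 (adjusted p = 5.27e-13, and adjusted p = 0.44 with an estimated correlation). This fall stood in the Cxxc1 KO cultures, where the median was −1.04 and 22 of 22 fell over the list alone (adjusted p = 2.03e-21, and adjusted p = 0.334 with an estimated correlation). In WT cultures the median was −0.01 (adjusted p = 0.777), and the difference between the genotypes is the interaction tested above. Among naive and quiescence genes Satb1 rose by 1.38 (SE 0.14) and Klf2 fell by 1.11 (SE 0.14), and 9 of 18 fell over the list alone (median −0.42, adjusted p = 0.000568, and adjusted p = 0.44 with an estimated correlation). Gzma, granzyme A, rose by 1.54 (SE 0.15), against the median of −0.48 of its cytotoxic list, in which Klrc1, an NK receptor gene, fell by 1.5 (SE 0.13) and 7 of 15 fell over the list alone (adjusted p = 0.000334, and adjusted p = 0.525 with an estimated correlation). Summed NK cell markers were also lower in Th2 than in Th1 in every cultured pair, in WT at 1.86 against 5.86 at 96 h and 6.47 against 7.64 at 120 h. The stress transcription factor gene Atf3 rose by 1.62 (SE 0.16) with 8 of 28 ATF4 response genes over the list alone (median 0.26, adjusted p = 2.04e-06, and adjusted p = 0.604 with an estimated correlation).

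Within WT cultures limma called 95 genes between Th2 and Th1, 63 higher and 32 lower (1393 unadjusted), and within Cxxc1 KO cultures 121, 54 higher and 67 lower (1465 unadjusted; 182 and 138 as deposited). In WT, Ecm1 rose by 3.25 (SE 0.29), Myo6 by 2.52 (SE 0.34) and Gata3 by 2.31 (SE 0.27, adjusted p = 0.0281), whereas Klrc1 fell by 1.52 and the cytokine gene Spp1 by 1.44. In Cxxc1 KO, Tanc2 rose by 2.94 and Gata3 by 2.6 (SE 0.16, adjusted p = 0.00545), and Ms4a4b (−3.29), Ifi203 (−2.38), Isg15 (−1.96) and Nkg7 (−1.21) fell. Without 96 h and without 120 h the WT counts were 2 and 3 and the Cxxc1 KO counts 37 and 19, and without 48 h they were 274 and 395.

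At single times in WT cells 113 genes were 2-fold apart between Th2 and Th1 cultures at 48 h (63 higher and 50 lower; 90 and 34 as deposited), 216 at 96 h (131 and 85) and 221 at 120 h (158 and 63; 114 and 141 as deposited). In Cxxc1 KO cells 291 were at 120 h (194 and 97; 123 and 108 as deposited). At 120 h in WT, scaled values in Th2 and Th1 were 24.56 and 0.24 for Il24, 24.70 and 0.27 for the steroidogenic enzyme gene Cyp11a1, 313.44 and 17.74 for Ecm1, 32.93 and 1.57 for Tnfrsf8, which encodes CD30, and 23.37 and 1.09 for Epas1. Wisp3 differed by 3.13. Il10 (16.43) and the enkephalin gene Penk (8.45) were listed at 0 in Th1. Lower in Th2 were Dapl1 (1.89 and 21.23), Prok1 (1.66 and 17.37), the IL-18 receptor gene Il18r1 (2.16 and 12.99) and the inhibitory receptor gene Btla (−2.36). Acsl6 (−2.31), Mgst2 (−2.23), Amica1 (−2.22) and Hba.a1 (−2.02) were lower too. In Cxxc1 KO at 120 h Tnfrsf8 differed by 4.09, Prok1 by −2.73 and Ms4a4b by −2.71, and Bc1 was listed at 0 in Th1. In WT at 48 h Defa4 and Snhg9 were listed at 0 in Th1, Ms4a4b differed by −3.34 and Mndal by −2.67. At 96 h Nfil3 had 74.14 and 4.08, Atp6v0c.ps2 and Atp6v0c stood apart, and Rps27, a ribosomal protein gene, differed by −5.07.

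Activation for 48 h replaced the naive program with growth and division genes in all 4 arms. Gzmb rose by 5.03 (SE 0.23, n = 4 arms, adjusted p = 8.53e-06) and Crabp2, which binds retinoic acid, by 4.38 (SE 0.40), while the globin genes Beta.s (−7.11) and Hbb.b2 (−6.93) fell. Of 18 naive and quiescence genes 16 fell over all genes and 17 when adjusted over the list alone, with a median of −2.43 (adjusted p = 3.59e-07, and adjusted p = 0.167 with an estimated correlation). The egress receptor gene S1pr1 (−5.0), the anti-proliferative genes Tob1 (−2.92) and Btg1 (−2.6) and the transcription factor gene Tcf7 (−2.69) fell. All 32 mitotic genes rose over all genes and over the list alone (median 2.47, adjusted p = 7.42e-15, and adjusted p = 0.167 with an estimated correlation), Top2a by 3.59, and so did all 26 histones (median 2.72, adjusted p = 8.51e-14, and adjusted p = 0.167 with an estimated correlation). Of glycolysis genes 16 of 17 rose over both (median 2.37, adjusted p = 0.504 with an estimated correlation), among them Tpi1 by 4.35 and the hexokinase gene Hk2 by 3.72. All 19 cholesterol genes (median 1.67, adjusted p = 0.504 with an estimated correlation) and all 24 oxidative phosphorylation genes (median 0.95, adjusted p = 0.167 with an estimated correlation) rose over both, with Cyp51 at 2.27 and Ndufa4 at 1.58. Of 26 genes induced by the T cell receptor 9 rose and 12 fell over both: Irf4 rose by 3.79, and the immediate early genes Fos (−5.39), Junb (−3.52) and Ier2 (−2.42) fell. Interferon-stimulated genes fell, 13 of 24 over both (median −0.92, adjusted p = 0.00245, and adjusted p = 0.794 with an estimated correlation). Summed markers of myeloid and NK cells fell beside them in each arm, in Th2 WT from 30.4 to 14.06 and from 7.23 to 2.89.

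In the lineage panel Tbx21 rose by 1.66 (SE 0.09), Il12rb2 by 1.53, Il4 by 2.00, Il13 by 1.25, Ccr8 by 1.87 and Ifng by 0.54 (SE 0.09, adjusted p = 0.00182), and Il18r1 fell by 2.51 and Cxcr3 by 1.02. Gata3 was not called over the 4 arms (−0.43, SE 0.56, adjusted p = 0.512), as it went from 15.45 to 3.60 in Th1 WT and from 16.66 to 37.23 in Th2 WT. Cxxc1 fell by 1.51 (SE 0.34), a mean that mixes activation with the deletion: it went from 16.24 to 8.77 in Th1 WT and from 16.01 to 1.73 in Th2 Cxxc1 KO. Trib3 rose by 0.36. Limma called 6924 of 10075 genes, 3462 in each direction (7229 unadjusted), and 2526 were at least 2-fold apart. The median of expressed genes was 0.23 as deposited and 0.07 scaled. Erythroid and platelet markers fell as well, 9 of 11 over all genes (median −1.89, adjusted p = 7.23e-05, and adjusted p = 0.251 with an estimated correlation): their sum went from 651.05 or more at 0 h to at most 8.71 in culture. In WT cells 2040 genes were 2-fold apart in Th1 (1086 higher, 954 lower) and 2174 in Th2 (1176 and 998; 1726 and 620 as deposited). Gzmb differed by 5.82 and 5.26, Prelid2 (25.82) and Akr1c18 (108.71) were listed at 0 at 0 h, and Hba.a1 differed by −7.01 in Th1.

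Between 48 and 96 h the early activation genes fell. Of 26 genes induced by the T cell receptor 23 fell and 1 rose over all genes, and 24 fell over the list alone, with a median of −1.32 (adjusted p = 5.42e-12, and adjusted p = 0.256 with an estimated correlation). The early response genes Nr4a1 (−3.41), Egr1 (−3.23), Egr2 (−3.06) and Egr3 (−2.87) were among them. Vim, vimentin, rose by 3.50 (SE 0.22, n = 4 arms, adjusted p = 0.000554) and Pglyrp2 by 3.14, and Crabp2 (−4.51) and Cd200 (−3.62) fell. Of 29 cytosolic ribosomal protein genes 21 fell over all genes and 24 over the list alone (median −0.44 scaled and −0.23 as deposited, adjusted p = 2.85e-09, and adjusted p = 0.256 with an estimated correlation). Of 12 inhibitory receptor genes 6 fell and 1 rose over both, Lag3 by 3.03 and Pdcd1, which encodes PD-1, by 2.35 (median −0.50, adjusted p = 0.012, and adjusted p = 0.436 with an estimated correlation). Naive genes came back in part, with 7 of 18 rising and 2 falling over both (median 0.38, adjusted p = 0.0436, and adjusted p = 0.436 with an estimated correlation): Igfbp4 rose by 3.03, S1pr1 by 2.58 and Klf2 by 1.97. Ifng fell by 1.84, Tbx21 by 1.33, Ccr8 by 1.15 and Il13 by 0.58, while Cxcr3 rose by 1.15, Il18r1 by 1.14 and Gata3 by 0.62. Limma called 2689 genes, 1370 higher and 1319 lower (4117 unadjusted), or 2376 and 679 as deposited, where the median of expressed genes was 0.20. Leaving out Th1 Cxxc1 KO, Th2 WT or Th2 Cxxc1 KO gave 1224, 1489 and 1719. In WT cells 490 genes were 2-fold apart in Th1 (279 and 211; 660 and 132 as deposited) and 383 in Th2 (228 and 155; 396 and 121 as deposited).

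Between 96 and 120 h division genes fell and cytotoxic and stress genes rose. Of 32 mitotic genes 30 fell over all genes and 31 over the list alone (median −0.70, adjusted p = 3.91e-22, and adjusted p = 0.37 with an estimated correlation), with Rrm2, a ribonucleotide reductase subunit, at −1.11 and the helicase gene Mcm2 at −0.99. Of 26 histones 25 fell over all genes and 26 over the list alone (median −0.87, adjusted p = 3.91e-22, and adjusted p = 0.37 with an estimated correlation), with Hist1h1a at −1.58. Of 15 cytotoxic and NK receptor genes 12 rose over both (median 0.97 scaled and 0.61 as deposited, adjusted p = 1.08e-05, and adjusted p = 0.37 with an estimated correlation): Gzma rose by 2.10, the perforin gene Prf1 by 1.62 and Gzmc by 1.43. Markers of other cell types rose with them: 3 of 5 NK cell markers over both, Klrb1c by 0.52, and 3 of 10 myeloid markers, Fcer1g by 1.96. In Th2 WT the myeloid sum went from 19.11 to 46.83 and the B cell sum from 15.92 to 37.85, and both sums were higher at 120 h in all 4 arms, except that as deposited the myeloid sum of Th1 Cxxc1 KO was lower. Of 28 ATF4 and amino acid stress genes 15 rose over all genes and 16 over the list alone (median 0.52 scaled and 0.14 as deposited, adjusted p = 0.00121, and adjusted p = 0.487 with an estimated correlation), Nupr1 by 1.95, Stc2 by 1.58 and Ddit4 by 1.36, and Trib3 rose by 1.31 (SE 0.21, n = 4 arms, adjusted p = 0.00879). Of 24 interferon-stimulated genes 12 rose and 1 fell over all genes (17 and 1 over the list alone), Usp18 by 0.81 (median 0.50 scaled and 0.26 as deposited, adjusted p = 0.000609, and adjusted p = 0.487 with an estimated correlation). The glucose transporter gene Slc2a3 rose by 2.48 among 8 of 17 glycolysis genes, 12 over the list alone (median 0.57 scaled and 0.15 as deposited, adjusted p = 0.487 with an estimated correlation), and 12 of 24 oxidative phosphorylation genes fell, 14 over the list alone (adjusted p = 0.37 with an estimated correlation). Among called genes at 5 or more, the 2 largest increases were Defa4 (2.92, uncertain) and the hypoxia-induced gene Ndrg1 (2.50), and the 2 largest decreases Hist1h1a and Gbp2 (−1.36). In the panel Il13 rose by 1.01 and Il18r1 by 0.64, and Cxcr3 fell by 0.56. Limma called 2353 genes, 1460 higher and 893 lower (4033 unadjusted), or 460 and 3033 as deposited, where the median of expressed genes was −0.40, and 982 and 1076 after quantile normalisation. Without Th2 WT, Th2 Cxxc1 KO or Th1 WT it called 767, 885 and 1122. In WT cells 282 genes were 2-fold apart in Th1 (229 and 53) and 398 in Th2 (282 and 116; 164 and 626 as deposited).

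Prolonged stimulation could be compared with regular stimulation only in Th2 WT cells under the 48 h label, 1 profile against 1. Multiples of this prolonged profile also stand under the 96 and 120 h labels, so its time in culture is not established. The differences below may therefore mix stimulation with time. The prolonged profile had more transcripts of the Th2 cytokine genes Il13, Il10, Il4 and Il24. Scaled values in prolonged and regular culture were 84.13 and 2.50 for Il13, 55.07 and 2.62 for Il10, 27.84 and 13.65 for Il4 and 91.13 and 2.75 for Il24. The cytokine gene Spp1 had 164.55 and 2.17, Penk 44.12 and 0.63, Basp1 45.14 and 1.07, the metallothionein genes Mt1 147.06 and 6.68 and Mt2 21.33 and 0.35, and Nkg7 51.69 and 2.06. On the Th1 side Il12rb2 had 61.00 and 6.13 and Tbx21 15.64 and 8.40, Ifng was under 2-fold apart at 7.25 and 6.13, and Gata3 had 53.15 and 37.23. Tcf7 (8.97 and 58.20), Il2 (2.25 and 13.87) and Hist1h1a (43.91 and 137.0) were lower, as were Actn1 (−1.95), Otud1 (−1.91), Edn1 (−1.56) and the uncertain Defa4 (−2.67), and Snhg9 was listed at 0 (12.08 in regular). In all 415 genes were 2-fold apart, 330 higher and 85 lower, or 274 and 206 as deposited, where the median of expressed genes was −0.21.

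Against the regular profile at 48 h and 10000 random lists matched on expression, the Th1 program (median 1.15, 17 of 20 genes higher), the Th2 program (1.00, 20 of 22), cytotoxic genes (1.12, 15 of 15), glycolysis (0.50, 17 of 17) and p53 response genes (0.51, 15 of 18) stood at percentile 100 in the prolonged profile. Random lists hold genes drawn independently, so these percentiles ignore correlation within a list and describe 1 profile against 1. Interferon-stimulated genes had a median of 0.33 at percentile 98.6 (0.15 after quantile normalisation), and IFN-γ response genes 0.43 at percentile 100. Mitotic genes (−0.44, 2 of 32 higher) and histones (−0.69, 0 of 26 higher) stood at percentile 0. Genes induced by the T cell receptor (−0.11, percentile 18.8) and naive genes (−0.10, percentile 36.7) lay within the random lists at 48 h. Against the regular profile at 96 h cytotoxic (1.16), glycolysis (0.46) and p53 response genes (0.64) stayed at percentile 100, and mitotic genes (−0.76) and histones (−1.17) at percentile 0. Interferon-stimulated genes stood there at percentile 79.5 (0.18) and IFN-γ response genes at percentile 2.5 (−0.35). Genes induced by the T cell receptor then stood at percentile 100 (1.24, and 0.73 against 120 h), and naive genes at percentile 1.7 (−0.37) and 0.4 against 120 h (−0.34). Several lists moved against the regular profile at 120 h: cytotoxic genes (0.02, percentile 56.9), glycolysis (0.06, percentile 77.5) and p53 response genes (0.13, percentile 87.3) then lay within the random lists. At 120 h mitotic genes turned to 0.12 (percentile 93.9), interferon-stimulated genes to −0.72 (percentile 0) and IFN-γ response genes to −0.36 (percentile 0.1), while the Th2 program (0.64) and the Th1 program (0.46) stayed at percentile 100 and histones (−0.43) at percentile 0. Beside these lists the B cell markers summed to 53.07 in the prolonged and 14.03 in the regular profile at 48 h, and the myeloid markers to 37.97 and 14.06. Across 10139 genes the prolonged profile correlated most with the Th2 WT regular profile at 48 h (r = 0.941), and next with Th2 Cxxc1 KO at 48 h (r = 0.933).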

Additional observations from a re-analysis of the deposited data

Results flagged for a closer look

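The difference of the KO effects between lineages was a test chosen after the data were seen, and so were the checks of the patterns below. Camera called 5 gene lists for that difference, Th2 minus Th1, and each lost the call with a correlation estimated from the residuals. The list medians were −0.97 for interferon-stimulated genes (adjusted p = 2.38e-31, and adjusted p = 0.219 with an estimated correlation) and −0.38 for IFN-γ response and antigen presentation genes (adjusted p = 1.62e-11). They were −0.34 for cytotoxic granule and NK receptor genes (adjusted p = 0.00435), −0.22 for the Th2 program (adjusted p = 0.0403) and 0.17 for cholesterol biosynthesis (adjusted p = 0.00228). For these 4 lists the result was adjusted p = 0.858 with an estimated correlation. In the cytotoxic list Gzmc (−1.18), Gzma (−1.12) and Nkg7 (−0.57) were lower when adjusted over the list alone, and in the Th2 program Cd24a (−1.31), Il24 (−1.19) and Il10 (−1.02). All 19 cholesterol genes had a positive difference and 0 passed over the list alone.

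The difference in interferon-stimulated genes did not rest on 1 time, because the lowest of the per-time differences between Th1 and Th2 medians was 0.61. A trait of the Cxxc1 KO mice that marks every profile would show at 0 h as well, where the list median was −0.11. The Th2 culture median of −0.07 is part of the pattern itself and is no separate check. Transcripts of other cell types remain possible: of 9 sums of B cell, NK and myeloid markers in Th1 cultures, 3 were higher in Cxxc1 KO. CD8 markers were higher in Cxxc1 KO in both lineages. What raised these genes in Th1 cultures is left open.

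Many files equal another file times whole percentages. Separate libraries would differ in which genes are listed at 0, but such pairs differed in at most 1 gene, against at least 105 between separate profiles. Rounding gives a highest share of 11% in the other pairs. A multiplication of each value by a whole percentage would give a spread that does not shrink with the level of the gene, and the SD of the log2 ratio fell by 6e-04 from genes at 5 to 20 to genes at 100 or more. Who or what made these files is not known from the sources used here.

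Cxxc1 showed no clear fall in the profiles labelled Cxxc1 KO at 0 h, with 14.67 against 16.24 and 16.01 against 16.12. A swap of labels at 0 h would give low Mid1 under the KO label, but the lowest Mid1 value there was 6.06, against at most 1.14 in WT. Cells of the same mice under both labels would have equal Mid1, but the smaller Mid1 difference was 1.73. A loss of the transcript that starts only in culture remains open, with a Cxxc1 difference of −0.07 at 0 h.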

How the results depend on the processing

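All fits described here were run after the data were seen, although quantile normalisation, the pseudocount of 0.1, the missing filter, the mean of at least 5, the second files and the estimated correlation had been planned. Fits with the 2 files of a group as replicates called 3036 to 8399 genes and are not valid, since a derived file adds no sample. No paired analysis was possible because every second file derives from another file, so replicate numbers mark no separate samples. The main fits pair profiles by time or arm. Cxxc1 in culture differed by −1.98 with a pseudocount of 0.1 and by −1.79 to −1.55 without 120 h or 96 h, and it then no longer passed over all genes, whereas second files gave −1.90. Second files are multiples of first files, so their counts and values cannot check a result. For KO against WT over both lineages limma called 1071 genes as deposited, 253 with a mean of at least 5, 2 without a filter and 0 with a pseudocount of 0.1 (1816 unadjusted). The same effect gave 1077 genes over 6 pairs of profiles, 300 from second files and 0 to 970 with a time left out. For Th1 alone limma called 561 as deposited, 42 with a mean of at least 5, 11 after quantile normalisation, 1 with a pseudocount of 0.1, 0 without a filter (1643 unadjusted), 149 from second files and 0 to 0 with a time left out (796 to 1977 unadjusted). For Th2 alone it called 831 as deposited, 3 with a mean of at least 5, 0 with a pseudocount of 0.1 (1467 unadjusted), 73 from second files and 0 to 7 with a time left out. The difference of KO effects between lineages had 18 calls from second files and 0 by limma in all other fits (398 to 805 unadjusted). Th2 against Th1 over both genotypes had 462 calls as deposited, 101 without a filter, 17 with a pseudocount of 0.1, 959 over 6 pairs and 18 to 711 with a time left out. In WT alone these were 378, 9 and 2, with 231 from second files and 2 to 274 with a time left out. In Cxxc1 KO alone they were 320, 33 and 23, with 19 to 395 with a time left out. For steps in time, 48 h against 0 h had 3964 calls with a mean of at least 5, while leaving out an arm gave 1224 to 1900 calls for 96 h against 48 h (lowest without Th1 Cxxc1 KO, then 1489 without Th2 WT and 1719 without Th2 Cxxc1 KO), and second files gave 2006. For 120 h against 96 h the range was 767 to 1976 (lowest without Th2 WT, then 885 without Th2 Cxxc1 KO and 1122 without Th1 WT). At 0 h limma called 4 genes as deposited, 1 after quantile normalisation, 1 without a filter, 0 with a mean of at least 5 (492 unadjusted), 7 from second files and 1 to 2 with a profile left out. Genes 2-fold apart between single profiles without the value floor numbered 57, 147, 233 and 430 for Cxxc1 KO against WT in Th1 at 0, 48, 96 and 120 h, and 59, 88, 224 and 438 in Th2. For Th2 against Th1 they numbered 50, 243, 354 and 381 in WT, and 41 at 0 h and 493 at 120 h in Cxxc1 KO. They were 580 and 647 for the later steps in Th2 WT and 699 for prolonged stimulation. As deposited, 973 genes differed by genotype in Th1 at 120 h, 200 and 644 in Th2 at 96 and 120 h, 792 between 48 and 96 h in Th1 WT and 790 between 96 and 120 h in Th2 WT. A pseudocount of 0.1 gave 29 and 30 genes for the KO label at 0 h, 22 between the WT profiles and 29 between the profiles labelled Cxxc1 KO. A mean of at least 5 gave 9 for the KO label at 0 h under the Th2 title. Second files gave 34 for that pair, 165 in Th2 at 96 h, 22 between the WT and 25 between the KO-labelled 0 h profiles. With an estimated correlation 0 of the 116 list calls stayed. The correlation of KO effects between lineages was 0.181, 0.321, 0.638 and 0.612 with a mean of at least 5, 0.534 and 0.484 after quantile normalisation at 96 and 120 h, and 0.614 and 0.663 as deposited. The direction within pairs can be given in 4 ways over 3 times and 8 ways over 4 arms, too few for a share under 0.05. The real direction was the 1 way with its count in all comparisons but 1: the difference of KO effects had 0 calls by limma in all 4 (698 unadjusted). The highest count of any other way was 1, for 120 h against 96 h, beside the real 2353. DESeq2 and a fit on counts were not run because the files hold no counts, and the cause was not tested where a count moved.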

Other observations

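All tests in this part were chosen after the results were seen. Regulatory T cell genes split at 48 h of culture over the 4 arms: 5 of 11 fell and 2 rose, both over all genes and when adjusted over the list alone. Foxp3, the regulator of regulatory T cells, fell by 2.02 (SE 0.09, n = 4 arms, limma adjusted p = 8.76e-06) and Ikzf2, which encodes Helios, fell by 1.48 (SE 0.09). The IL-2 receptor gene Il2ra rose by 3.56 (SE 0.18) and Tnfrsf18 by 1.81 (SE 0.11). The subunits of H3K4 methyltransferase complexes split too, with 6 of 14 up and 6 down over all genes: Mll1 fell by 1.47 (SE 0.09), Paxip1 rose by 1.01 and the shared subunit gene Dpy30 rose by 1.02 (SE 0.09). Among Tfh genes Pdcd1 rose by 2.4 and Btla by 1.26, while Cxcr5 fell by 1.26 and Bcl6 by 1.25. T cell identity genes fell, 13 of 15 over all genes (median −0.65, adjusted p = 0.00245, and adjusted p = 0.612 with an estimated correlation).

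Between 48 and 96 h heat shock genes fell, 8 of 13 over all genes (median −0.46, adjusted p = 0.000365, and adjusted p = 0.436 with an estimated correlation), with the chaperone gene Hspd1 at −1.29. IFN-γ response genes rose over the same step, 11 of 21 over all genes and 14 over the list alone (median 0.56, adjusted p = 0.000547, and adjusted p = 0.479 with an estimated correlation). From 96 to 120 h, 7 of 18 p53 response genes rose over all genes (median 0.32 scaled and 0.03 as deposited, adjusted p = 0.00271, and adjusted p = 0.487 with an estimated correlation), with Cdkn1a at 1.32 (SE 0.28). Over that step 6 of 12 inhibitory receptor genes rose (median 0.58 scaled and 0.30 as deposited, adjusted p = 0.0141, and adjusted p = 0.487 with an estimated correlation), among them Entpd1 by 1.00 and Havcr2 by 0.82. Myeloid markers rose beside them, 3 of 10, with Fcer1g at 1.96.

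Mid1 lies on the X chromosome next to the pseudoautosomal boundary, and Hbb.b1 belongs to a globin cluster that differs between mouse strains. As both separated the labels already at 0 h, where Cxxc1 differed by −0.07, their difference may come from the genetic background of the mice and not from the loss of Cxxc1. This is less certain for Hbb.b1, which has near-identical copies. The summed erythroid and platelet markers were also lower under the KO label at 0 h, at 651.05 and 834.08 against 992.64 and 1050.98 in WT. The smaller Mid1 difference at 0 h was 1.73, so the labels marked different mice. A measurement of Mid1 in Cre-negative littermates would separate these causes.

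The CD4-Cre transgene acts in the thymus, yet the Cxxc1 transcript at 0 h was at least 14.67 in all profiles and differed by −0.07. Cells that kept the gene could have been favoured before the sort, or the remaining transcript could lack the floxed exons, which a value per gene cannot show. Either state, if it did not change in culture, would keep Cxxc1 near the WT value there. Instead the mean scaled value in culture was 2.62 in Cxxc1 KO and 10.5 in WT, with Cxxc1 KO higher in 0 of 6 pairs. This argues against either state only if it stayed unchanged in culture and the cultures began from the cells at 0 h. The labels say neither, and values per gene cannot test it. A loss of the transcript that starts only in culture remains open. The lower values in culture, down to 1.73, also speak against intact cells taking over after activation. Reads per exon would be needed.

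Higher p53 targets stood beside lower histone, mitotic and cholesterol transcripts in cultured Cxxc1 KO cells. Calls for single genes were weak, with 0 genes called over both lineages by limma without 96 h (945 unadjusted) and 0 without 120 h (1050 unadjusted). No cell counts or cell cycle stages are in the samples used here, so whether fewer cells were dividing or cells were under DNA damage was not tested.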
